A study of Homo sapiens with 6 samples.

How the data were processed

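RNA-seq was analysed for 6 samples of the SW1990 pancreatic ductal adenocarcinoma cell line, 3 treated with 5 µM EPZ-5676 and 3 controls, grouped by their sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was enriched on oligo(dT) beads, and libraries were made with random priming and dUTP in the second strand, which marks strand. Reads were aligned with HISAT2 2.2.1 to GRCh38 (hg38), per the submitters' processing notes. The table deposited by the authors holds raw, whole-number read counts per gene and sample, with no normalization. The counting tool, its strand setting and the annotation release are not given in the sources used here. All 58735 genes of the table had the chromosome, start and end of GENCODE release 29, which was used for transcript GC content and length (the longest transcript per gene). Because oligo(dT) selection enriches polyadenylated RNA, histone and other mRNAs without a tail are under-represented.

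Counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr by group with its default minimum count of 10, TMM scaling, robust dispersion estimates and the two-sided quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. Totals of 33970420 to 39749648 reads per library left 15496 genes for testing, with a common dispersion of 0.0301. In data simulated from these libraries over the 15496 genes, 65 of 100 genes changed 2-fold and 39 of 100 genes changed 1.5-fold were recovered, with 3 false calls. Simulation also put a GC and length trend into the treated libraries: 3889 unchanged genes were then called without the correction described below and 8 with it. That trend was smooth in the properties the correction fits and equal in all treated libraries, so its removal was built in. The simulation does not show how the correction handles trends that differ between libraries, or treatment effects that follow GC content.

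Protein-coding genes were named by rule: past the threshold, mean log2 CPM of at least 1, all 3 treated libraries above or below all 3 controls, and the 12 largest changes in each direction; for other biotypes the 3 largest in each direction. DOT1L was named whatever its result. List members named as changed were among the 4 called members of the list with the smallest p, and those named as not past the threshold were among the most expressed. Some genes and a gene list are not reported here. Genes outside these rules are said to have been chosen after their values were seen.

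A total of 56 gene lists, of pathways, complexes, cell type markers and signs of RNA quality suited to a DOT1L inhibitor in pancreatic cancer cells, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, for the 51 lists with at least 5 tested genes. Fry and camera with an estimated correlation were run beside it; fry's directional p tests whether a list moves on balance one way and its mixed p whether its genes change in either direction, and neither compares the list with other genes. Of the list symbols, 4 had no match. The tests, the lists, the naming rule and a set of alternatives (RLE and upper-quartile scaling, other filters, DESeq2 1.42.0, limma-voom, a replicate block, protein-coding genes alone, and each library left out) were chosen before the data were examined.

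Corrections for GC content, for transcript length and for both were added after seeing the data. For each library a natural spline with 5 degrees of freedom per property was fitted to the deviation of log2 CPM from the gene mean, and the fitted trend was entered as an edgeR offset. A correction of this kind removes any treatment effect that follows GC content or length as well as technical trends. Intervals for list medians came from 1000 resamples of the members and those for correlations from 200 resamples of the genes. Both kinds treat genes as independent and hold the 6 libraries fixed, so they leave out the spread between libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.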

Results

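The series profiled polyadenylated RNA of SW1990, an established cell line of pancreatic ductal adenocarcinoma, with and without EPZ-5676. This small molecule inhibits DOT1L, a histone methyltransferase that modifies histone H3 in the bodies of transcribed genes. The question of the series was which genes differ in expression when DOT1L is inhibited. Treated cells received 5 µM of the compound. The sample characteristics describe the controls as untreated, whereas the treatment protocol gives them an equal volume of the solvent DMSO. The time of treatment is not given in the sources used here. The 3 control libraries held 38132352, 35042563 and 35568711 reads assigned to genes, and the 3 treated libraries 33970420, 34980138 and 39749648. Nothing in the labels says that replicates came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

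Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.977 to 0.981 between libraries of the same group and 0.954 to 0.975 between groups. The leading principal component of the 500 most variable genes held 35.4% of the variance. It placed the controls at -19.8, -11.0 and -14.2 and the treated libraries at 28.4, 9.69 and 6.84. On the next component (20.3%), treated replicate 1 stood apart at 17.8, with the other treated libraries at -18.9 and -14.1 and the controls at 5.61, 6.12 and 3.42. No pair of libraries was alike within sampling noise.

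EPZ-5676 was followed by changes in the mRNA of many genes. An anion exchanger, secreted epithelial proteins and a collagen VI chain were among the largest rises, and a complement inhibitor, an axon guidance ligand and a cytokine among the largest falls. Lists of genes of mitosis, DNA repair and the unfolded protein response of the endoplasmic reticulum were called lower by the set test camera, calls that did not hold with an estimated correlation (adjusted p = 0.611, 0.794 and 0.611). Of 15496 genes tested, 2326 were higher and 2899 lower in treated cells (adjusted p under 0.05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Changes of at least 2-fold were seen for 226 of the higher and 308 of the lower genes.

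The fold changes followed the GC content of the transcripts. Of the decile of genes with the lowest GC content, 763 were lower and 4 higher, and of the decile with the highest, 769 were higher and 6 lower. A step that removes smooth GC and length trends from each library, chosen after seeing the data and called the correction below, left 837 genes higher and 864 lower, of which 1114 had been called in the same direction before. Of all calls, 44.5% were higher, against 55.5% when length trends alone were removed. Without treated replicate 1 the uncorrected test called 1350 genes higher and 1884 lower, and without control replicate 1 it called 1753 lower. Genes lower by at least 2-fold numbered 146 without control replicate 1, 190 without treated replicate 1 and 488 without control replicate 2. With the correction, 397 were higher without treated replicate 1 and 523 without control replicate 3. The corrected count of lower genes was 512, 560 and 542 without treated replicates 1, 2 and 3, and 566 without control replicate 1.

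**Figure D1:**
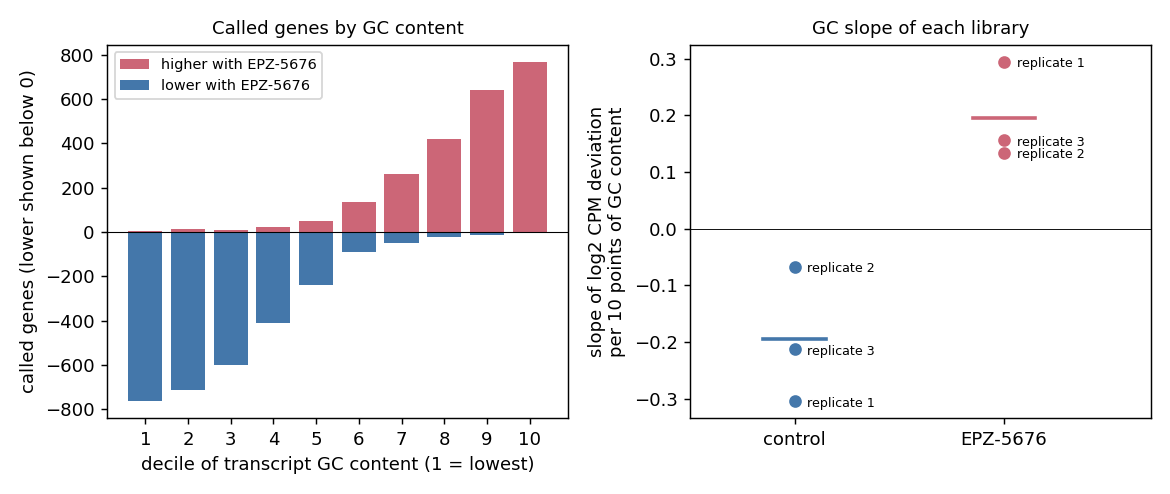
Called genes by decile of transcript GC content (left; bars above 0 count genes higher with EPZ-5676 and bars below 0 count genes lower), and the slope of each library's log2 CPM deviation on GC content per 10 percentage points (right; points are libraries, lines are group means, n = 3 each). Control slopes ran from -0.305 to -0.0674 and treated slopes from 0.134 to 0.295.

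The largest rises among protein-coding genes with a mean log2 CPM of at least 1, and with every treated library above every control, began with SLC4A3 (ENSG00000114923). This chloride and bicarbonate exchanger gene lies on chromosome 2, 219627327 to 219641980 (GRCh38). Its level was 0.938 ± 0.249 CPM in the controls and 5.55 ± 0.486 CPM in the treated cells (mean ± SD, n = 3 each), a log2 fold change of 2.56 ± 0.30 (SE; adjusted p = 1.6e-05). From here on, parentheses after gene names hold log2 fold changes ± SE, from before the correction unless stated. Genes said to have risen or fallen had an adjusted p under 0.05 in edgeR's quasi-likelihood test before the correction. Some genes named from lists did not pass after it. CCDC69 rose from 1.18 ± 0.461 to 5.39 ± 0.265 CPM, and the p53-inducible gene TP53I11 from 1.39 ± 0.317 to 6.35 ± 0.593 CPM. The potassium channel subunit KCNF1 (2.16 ± 0.37) and SRRM3 (2.12 ± 0.24), a splicing factor of neuronal microexons, also rose. Further rises were those of PALM3 (1.96 ± 0.34), GLIPR2 (1.96 ± 0.29), the secreted glycoprotein DMBT1 (1.85 ± 0.24), the aldehyde dehydrogenase ALDH3A1 (1.82 ± 0.30), NKAIN1 (1.66 ± 0.32) and the collagen VI chain COL6A2 (1.61 ± 0.21). The elastase inhibitor PI3 (1.67 ± 0.19) rose from 4.86 ± 0.418 to 15.5 ± 2.48 CPM. All 12 were past the threshold under each of 23 alternative settings. After the correction their log2 fold changes ran from 1.15 for COL6A2 to 2.15 for SLC4A3.

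The largest falls under the same rule were led by C4BPA (ENSG00000123838), which encodes the alpha chain of the complement inhibitor C4b-binding protein and lies on chromosome 1, 207104262 to 207144972. Its level was 12.2 ± 1.37 CPM in the controls and 2.18 ± 0.412 CPM in the treated cells (mean ± SD, n = 3 each), a log2 fold change of -2.48 ± 0.22 (adjusted p = 9.5e-07). The axon guidance ligand SLIT2 (-2.03 ± 0.34), the cationic amino acid transporter SLC7A2 (-1.58 ± 0.32), the glutamate receptor subunit GRIA4 (-1.58 ± 0.33), the placental alkaline phosphatase ALPP (-1.57 ± 0.16) and the protease inhibitor SPINK6 (-1.54 ± 0.21) fell. So did the cytokine IL18 (-1.51 ± 0.23), AP1S3 (-1.50 ± 0.19), TMEM168 (-1.50 ± 0.31), the ubiquitin ligase G2E3 (-1.49 ± 0.29), the heat shock cochaperone DNAJB4 (-1.48 ± 0.27) and the potassium channel KCNH5 (-1.48 ± 0.27). ALPP has a near-identical copy, so its count is uncertain. After the correction the log2 fold changes of these 12 genes ran from -2.11 for C4BPA to -0.89 for KCNH5, all past the threshold, although TMEM168 missed it when GC content alone was corrected (adjusted p = 0.0525). With the correction and a library left out, 6 of them missed it in some fits. DNAJB4 and SLC7A2 did so without control replicate 1 (0.0682 and 0.116) or treated replicate 1 (0.0621 and 0.0700), and GRIA4 without either of those or treated replicate 3 (0.0988, 0.0604 and 0.0780). G2E3 did so without any of controls 1 and 3 and treated replicates 1 and 2 (up to 0.0849), KCNH5 without any library but treated replicate 1 (up to 0.111), and TMEM168 without any of the 6 (up to 0.170).

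**Figure D2:**
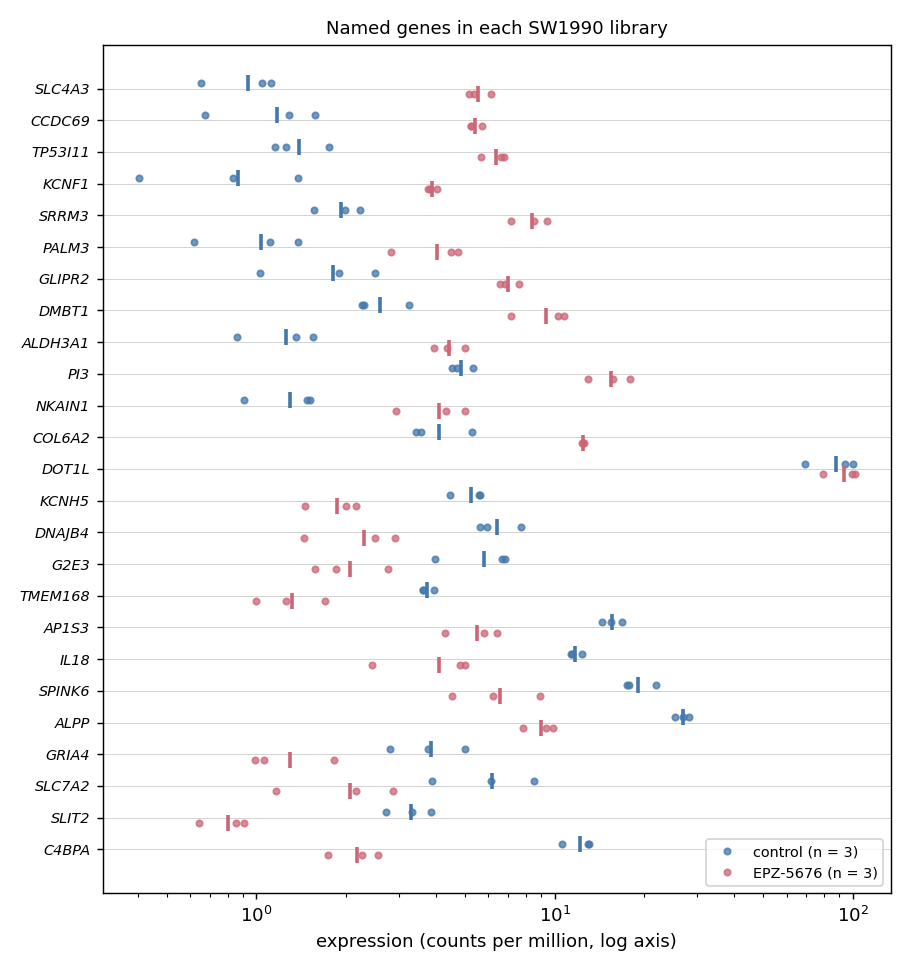
Expression of DOT1L and the 24 protein-coding genes named by rule, as CPM on a log axis, in each control (blue) and treated (red) library, where points are libraries and vertical bars are group means (n = 3 each). For every gene except DOT1L, the treated libraries lie wholly above or wholly below the controls.

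The mRNA of DOT1L (ENSG00000104885, chromosome 19, 2164149 to 2232578), the inhibitor's target, was at 69.4, 101 and 94.0 CPM in the controls and 102, 79.7 and 99.1 CPM in the treated libraries. Its log2 fold change was 0.09 ± 0.13 (adjusted p = 0.636), and -0.30 after the correction (adjusted p = 0.0375, against a range of 0.0119 to 0.924 over 23 alternatives). With the correction, the call was lost without any library but control replicate 1 (0.0604 to 0.199). EPZ-5676 acts on the protein, so this level does not check the labels. In the list of DOT1L partners and elongation factors, 12 of 25 genes were lower and 2 higher (14 and 3 adjusted over the list alone, 3 and 2 after the correction, camera adjusted p = 0.305). Here and in the list counts below, camera's p in such parentheses is the value before the correction. The nucleolar histone chaperone NPM1 (-0.84 ± 0.12), the cyclin CCNT2 (-1.22 ± 0.24) and the elongation factor ELL2 (-0.60 ± 0.13) fell, and the elongation kinase CDK9 (0.52 ± 0.10) rose. Among HOXA and MEIS genes, 3 of 14 genes were lower and 1 higher (2 and 1 adjusted over the list alone, 2 and 0 after the correction, camera adjusted p = 0.800). HOXA9 fell from 1.46 ± 0.0861 to 0.313 ± 0.272 CPM (adjusted p = 0.00646), HOXA10 (-0.61 ± 0.23) fell too, and MEIS3 (0.43 ± 0.12) rose. Among HOXB, HOXC and HOXD genes, 2 of 18 genes were higher and 0 lower (2 and 0 adjusted over the list alone, 2 and 0 after the correction, camera adjusted p = 0.611), and HOXD9 (1.29 ± 0.26) and HOXB13 (0.83 ± 0.20) rose.

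Camera called the list of G2/M and mitosis lower. In that list, 35 of 45 genes were lower and 0 higher (36 and 0 adjusted over the list alone, 21 and 0 after the correction, camera adjusted p = 9.2e-09). The mitotic kinase CDK1 (-1.13 ± 0.13), the cyclin CCNA2 (-1.02 ± 0.12) and the spindle checkpoint genes MAD2L1 (-0.82 ± 0.11) and BUB1B (-1.04 ± 0.15) fell. The survivin gene BIRC5 (-0.06 ± 0.10) and the ubiquitin carrier gene UBE2C (0.01 ± 0.09) did not pass. After the correction MAD2L1 (-0.29, edgeR adjusted p = 0.067) did not pass either. The list's median was -0.66, and -0.33 after the correction. Camera's call gave an adjusted p = 0.611 with an estimated correlation, but held after the correction (2.8e-11, and 0.0786 with an estimated correlation) and in the other settings (1.3e-11 to 9.1e-08 over 22 alternatives). In the list of G1/S and DNA replication, 17 of 45 genes were lower and 5 higher (20 and 5 adjusted over the list alone, 10 and 0 after the correction, camera adjusted p = 0.0825). The ribonucleotide reductase subunit RRM1 (-0.81 ± 0.12), the sliding clamp PCNA (-0.55 ± 0.10) and the clamp loader RFC3 (-0.82 ± 0.17) fell. After the correction RFC3 (-0.30, edgeR adjusted p = 0.150) did not pass.

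Camera called the list of DNA repair genes lower. In that list, 19 of 41 genes were lower and 0 higher (19 and 0 adjusted over the list alone, 6 and 0 after the correction, camera adjusted p = 7.5e-05). RAD51AP1 (-1.24 ± 0.20), the Fanconi anemia gene FANCI (-0.89 ± 0.14), the end-joining gene XRCC5 (-0.74 ± 0.13) and the damage kinase ATM (-0.89 ± 0.17) fell, while PARP1 (-0.06 ± 0.10) did not pass. After the correction ATM (-0.33, edgeR adjusted p = 0.170) did not pass. The list's median was -0.53, and -0.20 after the correction. The call had an adjusted p = 0.794 with an estimated correlation, and camera's adjusted p was 0.00694 after the correction (0.517 with an estimated correlation; range 2.0e-06 to 0.0200 over 22 alternatives). Among p53 targets and CDK inhibitors, 9 of 28 genes were higher and 7 lower (9 and 8 adjusted over the list alone, 3 and 4 after the correction, camera adjusted p = 0.753). CDKN1A (0.59 ± 0.10), PHLDA3 (0.57 ± 0.10) and BAX (0.68 ± 0.11) rose and CDKN1B (-0.64 ± 0.10) fell. Among apoptosis promoters, 7 of 23 genes were higher and 5 lower (8 and 7 adjusted over the list alone, 3 and 1 after the correction, camera adjusted p = 0.858), with BAD (0.65 ± 0.13) higher and CYCS (-0.67 ± 0.12) lower. Among apoptosis inhibitors, 4 of 10 genes were lower and 1 higher (4 and 1 adjusted over the list alone, 1 and 0 after the correction, camera adjusted p = 0.337), with BIRC3 (-1.14 ± 0.27) and MCL1 (-0.40 ± 0.11) lower and BCL2L1 (0.35 ± 0.10) higher. After the correction BCL2L1 was no longer called higher, and at most 1 of BIRC3 and MCL1 was lower.

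Several chaperones of the endoplasmic reticulum fell. In the list of its unfolded protein response, 10 of 22 genes were lower and 0 higher (13 and 1 adjusted over the list alone, 7 and 0 after the correction, camera adjusted p = 0.0144). The chaperones HSP90B1 (-1.02 ± 0.12), CANX (-0.83 ± 0.11) and HSPA5 (-0.54 ± 0.10) and the disulfide isomerase PDIA6 (-0.56 ± 0.10) fell, and the chaperone CALR (-0.05 ± 0.10) did not pass. The call had an adjusted p = 0.611 with an estimated correlation. The correction moved the median from -0.32 to -0.19 and left the call past the threshold (adjusted p = 0.0107, but 0.517 with an estimated correlation; range 0.00198 to 0.0544 over 22 alternatives). The call was lost without treated replicate 2 (0.0518) and, with the correction, without treated replicate 3 (0.0544). Among heat shock proteins, 7 of 18 genes were lower and 2 higher (7 and 2 adjusted over the list alone, 6 and 0 after the correction, camera adjusted p = 0.535 before it). The mitochondrial chaperone HSPD1 (-1.05 ± 0.12) and the cytosolic HSP90AA1 (-0.89 ± 0.16) and DNAJA1 (-0.69 ± 0.12) fell. Among genes of ATF4 and amino acid stress, 8 of 31 genes were lower and 3 higher (8 and 3 adjusted over the list alone, 10 and 0 after the correction, camera adjusted p = 0.920 before it). The serine synthesis enzyme PSAT1 (-0.87 ± 0.10), the folate enzyme MTHFD2 (-0.89 ± 0.12) and the glycyl-tRNA synthetase GARS (-0.66 ± 0.10) fell.

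Most of the glycolysis genes that changed rose. In that list, 12 of 23 genes were higher and 4 lower (13 and 4 adjusted over the list alone, 6 and 1 after the correction, camera adjusted p = 0.0237). PFKFB4 (0.51 ± 0.10), ALDOA (0.60 ± 0.12) and ENO2 (0.47 ± 0.10), which act in sugar breakdown or its control, rose, and the lactate transporter SLC16A1 (-0.69 ± 0.13) fell. The call had an adjusted p = 0.794 with an estimated correlation. It was lost after the correction (0.122), which moved the median from 0.27 to 0.09, without treated replicate 2 (0.0518) and with a replicate block (0.0539), in a range of adjusted p of 0.00678 to 0.324 over 22 alternatives. Camera also called the list of immediate early genes, whose products respond quickly to growth signals, higher, while the directional test fry did not (adjusted p = 0.0792). There, 9 of 23 genes were higher and 1 lower (9 and 1 adjusted over the list alone, 2 and 1 after the correction, camera adjusted p = 0.0237). JUND (0.67 ± 0.12), JUNB (0.44 ± 0.10), FOS (0.43 ± 0.11) and KLF2 (0.94 ± 0.24) rose, while JUN (-0.01 ± 0.10) did not pass. After the correction FOS (0.33) was still higher and JUN (-0.25) was lower, while JUND (0.16), JUNB (-0.0029) and KLF2 (0.51) did not pass. The call had an adjusted p = 0.794 with an estimated correlation. It was lost after the correction (0.293), which moved the median from 0.22 to 0.07, and without treated replicate 2 (0.0587), in a range of 0.00445 to 0.510 over 22 alternatives.

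Camera called the list of neuronal and neuroendocrine genes higher. In that list, 3 of 9 genes were higher and 0 lower (3 and 0 adjusted over the list alone, 3 and 0 after the correction, camera adjusted p = 0.0237). The microtubule protein gene MAPT (0.98 ± 0.15), the axonal DPYSL3 (0.86 ± 0.19) and ENO2 (0.47 ± 0.10), which is also in the glycolysis list, rose. The secretory granule genes SCG5 (0.62 ± 0.30) and SCG2 (-0.84 ± 0.49) did not pass. Of 30 genes in the list, 9 were tested, and the 6 not past the threshold were weakly expressed. Their control means ran from 0.483 CPM for MAP2 to 2.34 CPM for SCG5. The call had an adjusted p = 0.611 with an estimated correlation. The correction moved the median from 0.62 to 0.37 and left the call past the threshold (adjusted p = 0.0149, but 0.517 with an estimated correlation; range 0.00508 to 0.0937 over 22 alternatives). The call was lost without control replicate 3 (0.0545, and 0.0681 with the correction), treated replicate 2 (0.0518) or treated replicate 3 (0.0937, and 0.0593 with the correction).

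Camera, run with a preset inter-gene correlation, compared each list with all other genes and called 3 lists higher and 3 lower of 51 tested. No call held with camera's estimated correlation, which left 3 lists at an unadjusted p under 0.05. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, called 12 lists. Camera called 13 lists after the correction, 4 of them also called before it, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Median, mean and camera's direction had 1 sign in each of the 6 called lists and differed in 11 others. These were p53 targets, nuclear oxidative phosphorylation, replication-dependent histones, fatty acid oxidation, ribosomal proteins, integrins, apoptosis promoters, ATF4 targets, chromatin modifiers, YAP targets and the basal-like subtype.

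**Figure D3:**
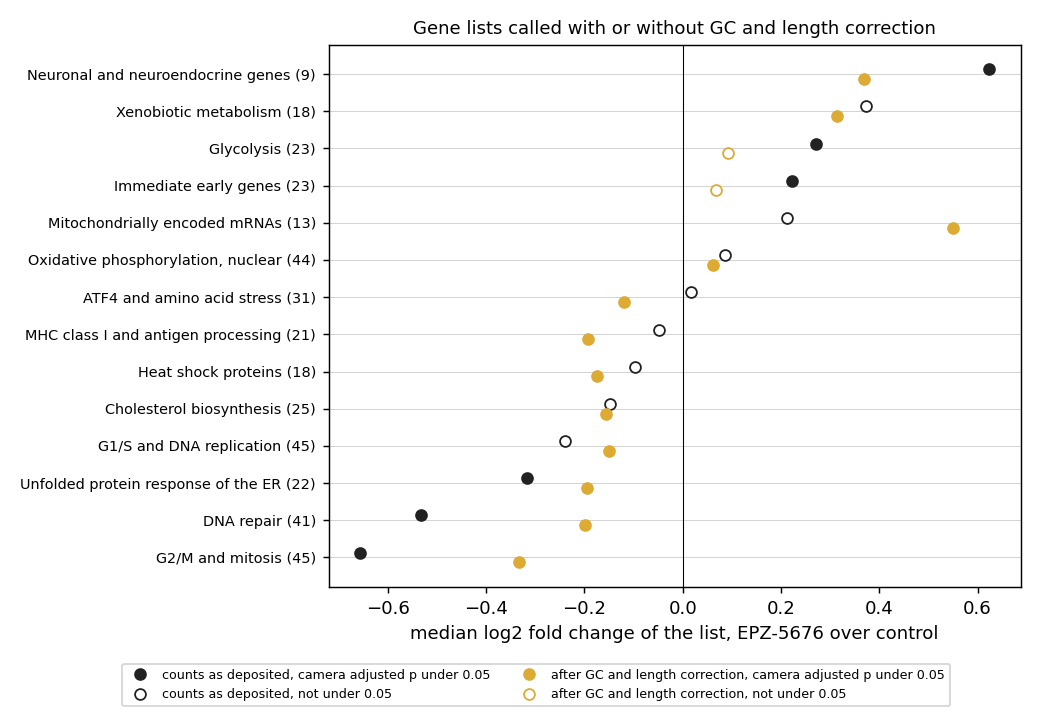
Median log2 fold change (EPZ-5676 over control) of gene lists called by camera before or after GC and length correction and reported here, with the number of tested genes in parentheses. Black points are the counts as deposited, yellow points follow the correction, and open points had an adjusted p of at least 0.05; the G2/M and mitosis list had the lowest median before (-0.66) and after (-0.33) the correction.

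Other metabolic lists were not called before the correction. In cholesterol biosynthesis, 7 of 25 genes were lower and 2 higher (9 and 2 adjusted over the list alone, 8 and 0 after the correction, camera adjusted p = 0.401). The synthase HMGCS1 (-1.12 ± 0.17), the sterol oxidase MSMO1 (-1.02 ± 0.15) and the sterol sensor INSIG1 (-0.73 ± 0.10) fell. In fatty acid synthesis, 8 of 25 genes were lower and 4 higher (10 and 5 adjusted over the list alone, 5 and 1 after the correction, camera adjusted p = 0.761), and the desaturases SCD (-0.64 ± 0.11) and FADS1 (-0.55 ± 0.10) fell. In fatty acid oxidation, 6 of 23 genes were higher and 5 lower (8 and 7 adjusted over the list alone, 3 and 2 after the correction, camera adjusted p = 0.800). The coactivator PPARGC1A (-1.29 ± 0.27) and the dehydrogenase ACADM (-1.04 ± 0.21) fell, and the related ACADS (0.66 ± 0.10) rose. Of nuclear genes of oxidative phosphorylation, 7 of 44 genes were higher and 7 lower (7 and 7 adjusted over the list alone, 6 and 0 after the correction, camera adjusted p = 0.611). Of mitochondrially encoded mRNAs, 4 of 13 genes were higher and 0 lower (2 and 0 adjusted over the list alone, 9 and 0 after the correction, camera adjusted p = 0.0830), and MT-ND1 (0.48 ± 0.15) and MT-CO2 (0.34 ± 0.12) rose. In the hypoxia response, 11 of 24 genes were lower and 4 higher (11 and 5 adjusted over the list alone, 7 and 3 after the correction, camera adjusted p = 0.680), and ERO1A (-0.86 ± 0.12) and P4HA1 (-0.81 ± 0.11) fell.

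In xenobiotic metabolism, 5 of 18 genes were higher and 1 lower (5 and 1 adjusted over the list alone, 3 and 0 after the correction, camera adjusted p = 0.0930), and the glutathione transferases GSTP1 (0.68 ± 0.10) and GSTM3 (0.43 ± 0.12) rose with ALDH3A1. Of NRF2 targets, 6 of 28 genes were higher and 7 lower (8 and 7 adjusted over the list alone, 5 and 2 after the correction, camera adjusted p = 0.611). The ferritin chain FTH1 (0.65 ± 0.12) rose, and the thioredoxin reductase TXNRD1 (-0.65 ± 0.12) fell. Of ferroptosis regulators, 8 of 22 genes were lower and 4 higher (8 and 5 adjusted over the list alone, 1 and 3 after the correction, camera adjusted p = 0.832), with the peroxidase GPX4 (0.56 ± 0.11) higher. Of autophagy and lysosome genes, 11 of 42 genes were higher and 11 lower (11 and 11 adjusted over the list alone, 6 and 3 after the correction, camera adjusted p = 0.611). In gemcitabine transport and metabolism, 7 of 15 genes were lower and 3 higher (7 and 3 adjusted over the list alone, 1 and 1 after the correction, camera adjusted p = 0.428). There the activating kinase DCK (-0.71 ± 0.15) fell and the inactivating deaminase CDA (0.52 ± 0.11) rose. Of ABC transporters, 3 of 15 genes were higher and 1 lower (3 and 1 adjusted over the list alone, 0 and 0 after the correction, camera adjusted p = 0.985). The drug exporter ABCC2 (-1.06 ± 0.29) fell before the correction but did not pass after it.

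Camera called none of the Notch, Wnt, TGF-beta and YAP lists before or after the correction, although the Notch list was called higher without a filter on low counts (adjusted p = 0.0373). In the Notch pathway, 5 of 18 genes were higher and 2 lower (5 and 3 adjusted over the list alone, 1 and 1 after the correction, camera adjusted p = 0.126). The ligand JAG2 (0.82 ± 0.15) and the receptor NOTCH3 (0.85 ± 0.23) rose and the transcription factor RBPJ (-0.58 ± 0.16) fell. At most 1 of these rises held after the correction. Of Wnt targets, 4 of 18 genes were higher and 0 lower (3 and 0 adjusted over the list alone, 1 and 1 after the correction, camera adjusted p = 0.288), and the ligand WNT7B (0.91 ± 0.13) and the antagonist NKD2 (1.38 ± 0.30) rose. Here too, at most 1 of the named rises held after the correction. Of TGF-beta targets, 5 of 25 genes were higher and 3 lower (4 and 3 adjusted over the list alone, 2 and 5 after the correction, camera adjusted p = 0.511). The activin subunit INHBA (1.30 ± 0.18) rose and the receptor TGFBR1 (-0.88 ± 0.15) fell. Of YAP targets, 5 of 23 genes were lower and 1 higher (5 and 1 adjusted over the list alone, 4 and 2 after the correction, camera adjusted p = 0.939), and the factor TEAD1 (-0.77 ± 0.16) fell.

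Inflammatory and immune genes moved both ways. In the list of NF-kB and inflammatory cytokines, 5 of 27 genes were higher and 3 lower (5 and 3 adjusted over the list alone, 7 and 1 after the correction, camera adjusted p = 0.423). The cytokines IL1B (1.47 ± 0.35) and IL11 (0.72 ± 0.11) rose, and SOD2 (-0.77 ± 0.11) and BIRC3 (-1.14 ± 0.27) fell. At most 1 of these falls held after the correction. In the type I interferon response, 5 of 35 genes were lower and 3 higher (5 and 3 adjusted over the list alone, 2 and 0 after the correction, camera adjusted p = 0.858), with PARP14 (-0.82 ± 0.19) lower. In MHC class I and antigen processing, 4 of 21 genes were lower and 0 higher (3 and 0 adjusted over the list alone, 5 and 0 after the correction, camera adjusted p = 0.800). B2M (-0.77 ± 0.11), the light chain of MHC class I, fell.

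Genes of cell identity and adhesion also moved both ways. Of epithelial genes, 6 of 25 genes were higher and 0 lower (6 and 0 adjusted over the list alone, 1 and 1 after the correction, camera adjusted p = 0.245). The junction genes PKP3 (0.46 ± 0.11), JUP (0.46 ± 0.12) and CLDN4 (0.39 ± 0.11) and the protease inhibitor SPINT1 (0.94 ± 0.22) rose. Most of these rises did not hold after the correction, which left 1 gene of the list higher. Of mesenchymal genes, 6 of 29 genes were higher and 2 lower (5 and 2 adjusted over the list alone, 2 and 2 after the correction, camera adjusted p = 0.611). In extracellular matrix and collagens, 8 of 39 genes were higher and 7 lower (10 and 8 adjusted over the list alone, 5 and 9 after the correction, camera adjusted p = 0.511), and the collagen chains COL5A3 (1.40 ± 0.15) and COL6A1 (0.82 ± 0.11) rose with COL6A2. Of proteases and inhibitors of invasion, 9 of 30 genes were higher and 4 lower (9 and 4 adjusted over the list alone, 6 and 0 after the correction, camera adjusted p = 0.337). PLAU (0.69 ± 0.15), TIMP1 (0.56 ± 0.11) and MMP2 (0.50 ± 0.10) rose and ADAM9 (-0.83 ± 0.14) fell, although ADAM9 was not called lower after the correction. Of integrins, 4 of 13 genes were lower and 2 higher (4 and 2 adjusted over the list alone, 6 and 1 after the correction, camera adjusted p = 0.832), and ITGB1 (-1.10 ± 0.13), ITGA1 (-1.18 ± 0.18) and ITGA6 (-0.86 ± 0.13) fell.

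Of genes of the basal-like subtype of pancreatic cancer, 2 of 19 genes were higher and 2 lower (2 and 2 adjusted over the list alone, 1 and 5 after the correction, camera adjusted p = 0.985), with KRT17 (0.31 ± 0.11) higher. Of genes of the classical subtype, 1 of 8 genes was lower and 0 higher (1 and 0 adjusted over the list alone, 1 and 0 after the correction, camera adjusted p = 0.927), through TSPAN8 (-1.22 ± 0.23). Of pancreatic ductal markers, 2 of 9 genes were lower and 1 higher (2 and 1 adjusted over the list alone, 1 and 2 after the correction, camera adjusted p = 0.985), and of cancer stem cell genes, 3 of 14 genes were lower and 2 higher (3 and 2 adjusted over the list alone, 3 and 2 after the correction, camera adjusted p = 0.680). The ductal factor SOX9 (0.47 ± 0.15) rose and the receptor MET (-0.75 ± 0.15) fell.

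Markers of other cell types were few among the tested genes. Of fibroblast markers, 3 of 10 genes were higher and 2 lower (3 and 2 adjusted over the list alone, 0 and 0 after the correction, camera adjusted p = 0.611), and of endothelial markers, 1 of 5 genes was higher and 0 lower (1 and 0 adjusted over the list alone, 0 and 0 after the correction, camera adjusted p = 0.680). Fewer than 5 genes were tested, and no list test was run, for 5 lists. Of leukocyte markers 1 of 4 genes was higher and 0 lower (1 and 0 adjusted over the list alone, 0 and 0 after the correction). Of metallothioneins 2 of 4 genes were higher and 0 lower (2 and 1 adjusted over the list alone, 1 and 1 after the correction). Of the 2 MHC class II genes, the 1 mucin and the 2 pancreatic acinar markers tested, 0 were past the threshold over all genes, adjusted over the list alone or after the correction.

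Of cytosolic ribosomal proteins, 12 of 63 genes were higher and 13 lower (13 and 13 adjusted over the list alone, 8 and 6 after the correction, camera adjusted p = 0.800). Of MYC targets in ribosome biogenesis, 10 of 39 genes were higher and 8 lower (12 and 11 adjusted over the list alone, 1 and 5 after the correction, camera adjusted p = 0.985), with MYC at -0.23 ± 0.11, not past the threshold. Of chromatin modifiers, 12 of 49 genes were lower and 9 higher (13 and 9 adjusted over the list alone, 3 and 2 after the correction, camera adjusted p = 0.927), and the deacetylase SIRT1 (-1.41 ± 0.19) and the methyltransferase NSD2 (-0.51 ± 0.10) fell. Of replication-dependent histones, whose mRNAs mostly lack a poly(A) tail and whose copies are near-identical, 4 of 20 genes were higher and 2 lower (4 and 2 adjusted over the list alone, 3 and 1 after the correction, camera adjusted p = 0.762). Of long noncoding RNAs, 3 of 15 genes were lower and 0 higher (3 and 0 adjusted over the list alone, 1 and 2 after the correction, camera adjusted p = 0.680), and the nuclear RNAs MALAT1 (-0.95 ± 0.13) and NEAT1 (-0.62 ± 0.11) fell. After the correction at most 1 of MALAT1 and NEAT1 was lower.

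Of 12632 protein-coding genes tested, 2234 were higher and 2748 lower, and of 685 intergenic long noncoding genes, 27 and 28. Outside protein-coding genes, the largest rises under the naming rule were AC116351.2 (1.39 ± 0.31), AC012236.1 (1.24 ± 0.29) and ELFN1-AS1 (1.15 ± 0.20). The largest falls were AC027290.2 (-1.44 ± 0.42) and MIR100HG (-1.40 ± 0.35) and the pseudogene EIF4EP2 (-1.39 ± 0.38). The 3 rises were past the threshold after the correction and the 3 falls were not (adjusted p = 0.0696, 0.0948 and 0.0993, in ranges of 0.00111 to 0.288, 0.00168 to 0.321 and 6.2e-04 to 0.355). AC027290.2 also missed it without control replicate 1 (0.0943) or treated replicate 1 (0.0588), and EIF4EP2 without control replicate 3 (0.0589). With the correction, AC116351.2 missed it without any library but control replicate 2 (up to 0.0933) and AC012236.1 without treated replicate 3 (0.0611). Antisense and pseudogene counts are uncertain, since the strand setting of the counting is not given in the sources used here.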

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

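The corrections for GC content and length, alone, together and with a library left out, were chosen after seeing the data; the other alternatives were planned. RLE and upper-quartile scaling, both other filters, limma-voom, DESeq2 and protein-coding genes alone kept the gene counts within 1.5 times, and the 31 named genes tested under each kept their direction and side of the threshold; for protein-coding genes alone that covers 25. The 2 scalings left all 51 lists where they stood. DESeq2 gave no list test. The share of higher calls was 44.5%, and 49.9% with RLE, 50.6% with DESeq2 and 55.5% with the length correction. Without a filter 5 lists were higher, with the Notch pathway (adjusted p = 0.0373) and mitochondrially encoded mRNAs (0.0373) gained, and the lower lists gained G1/S and DNA replication (0.0373). In place of camera's preset correlation, fry called 9 lower, and an estimated correlation left 0 higher and 0 lower. Limma-voom also called mitochondrially encoded mRNAs higher (0.0198).

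GC correction called 762 genes higher and 730 lower (113 and 50 by at least 2-fold) and 8 lists lower. The GC and length correction called 837 and 864 (115 and 51), with 5 lists higher and 8 lower. Of 534 genes changed at least 2-fold, 268 were called after it, and the SD of all log2 fold changes went from 0.581 to 0.467; fewer calls follow from the removed trend. The log2 fold change of DOT1L turned to -0.30 under the GC correction (adjusted p = 0.0484) and -0.30 under both (adjusted p = 0.0375), against a range of adjusted p from 0.0119 to 0.924 over 23 alternatives. With a library left out it ran from -0.05 to 0.21 without the correction and from -0.38 to -0.22 with the GC and length correction. The corrected call was lost without any library but control replicate 1 (0.0604 to 0.199), and the cause was not tested.

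With each library left out, higher genes numbered 1350 to 2780 and lower genes 1753 to 3167, by at least 2-fold 177 to 315 and 146 to 488, and lists 0 to 5 higher and 2 to 4 lower. With the GC and length correction as well, the ranges were 397 to 856 and 512 to 815, 78 to 144 and 28 to 67, and 2 to 4 and 5 to 9; the fewest genes were called without treated replicate 1 and the fewest lists without treated replicate 3. A fit with fewer libraries has less power. Of the 31 named genes, 4 to 10 lost their call in these corrected fits. In simulated data at these 33970420 to 39749648 reads per library, 65 of 100 changes of 2-fold and 39 of 100 of 1.5-fold were recovered, so unchanged cannot be read from a gene that was not called. The simulation gave 107 calls, against 5225 in the data, which makes its adjusted threshold stricter. Its shares therefore do not measure recovery in the data themselves.

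The labels state no pairing by replicate number. Deviations of same-numbered samples from their group means correlated at -0.111, -0.0927 and 0.0466, and those of other pairs at -0.0799 to 0.155. Such deviations also hold the GC trends of single libraries, so this check can neither show nor exclude shared batches. With the number as a replicate block, 1677 genes were higher and 2219 lower (210 and 290 by at least 2-fold), 3883 of these 3896 calls being shared, and 2 lists were higher and 3 lower. The glycolysis list was the list that lost its call (adjusted p = 0.0539).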

Other observations

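Tests of library slopes on GC content, of sequencing depth, of a smaller share of dividing cells and of the clock genes, and every value after the GC and length correction, were chosen only after the result was seen. After the correction, camera called 9 lists that it had not called before, none of which held with an estimated correlation. Among them were G1/S and DNA replication (median -0.24 before and -0.15 after it, adjusted p = 0.00364, 0.00227 to 0.168 over 22 alternatives), cholesterol biosynthesis (median -0.15 before and -0.16 after it, adjusted p = 0.00379, 0.00102 to 0.608 over 22 alternatives), heat shock proteins (median -0.10 before and -0.17 after it, adjusted p = 0.00530, 0.00366 to 0.652 over 22 alternatives) and mitochondrially encoded mRNAs (median 0.21 before and 0.55 after it, adjusted p = 1.0e-05, 1.4e-06 to 0.370 over 22 alternatives). These 4 were called with the correction whichever library was left out, but had an adjusted p = 0.289 to 0.661 with an estimated correlation. The share of reads on mitochondrial genes overlapped between the groups, at 2.36, 2.77 and 2.71% in the controls and 2.56, 2.47 and 2.57% in the treated libraries. That share also holds the mitochondrial ribosomal RNAs, of which 2 of 2 tested were lower before the correction (median -0.51) and 0 after it. Other lists lost the call without some libraries. MHC class I and antigen processing (median -0.05 before and -0.19 after it, adjusted p = 0.0149, 0.00558 to 0.964 over 22 alternatives) lost it without control replicate 2 (0.0640), treated replicate 2 (0.0878) and treated replicate 3 (0.0708), and the ATF4 list (median 0.02 before and -0.12 after it, adjusted p = 0.0166, 0.00672 to 0.988 over 22 alternatives) without treated replicate 2 (0.114) and treated replicate 3 (0.0708). Nuclear oxidative phosphorylation (median 0.09 before and 0.06 after it, adjusted p = 0.0346, 0.0177 to 0.976 over 22 alternatives) lost it without control replicate 3 (0.490), treated replicate 1 (0.248) and treated replicate 3 (0.0549). Xenobiotic metabolism (median 0.37 before and 0.31 after it, adjusted p = 0.0476, 0.0140 to 0.260 over 22 alternatives) lost it without control replicate 1 (0.0809), control replicate 2 (0.116), treated replicate 2 (0.0793) and treated replicate 3 (0.140). Ranges are of adjusted p over the settings tried.

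The genes in this paragraph were chosen after their values were seen. The activin subunit INHBA (1.30 ± 0.18 before and 1.83 after the correction) rose, and INHA (-0.76 ± 0.19 before and -1.16 after the correction), the inhibin subunit that pairs with it, fell. C4BPB, the beta chain of C4b-binding protein, fell with C4BPA, from 1.01, 1.26 and 1.10 CPM in the controls to 0.0644, 0 and 0.0759 CPM in the treated libraries (adjusted p = 4.5e-04), and ALPI (-1.44 ± 0.11 before and -1.84 after the correction), the related intestinal alkaline phosphatase, fell with ALPP. The ubiquitin ligase FBXO32 (1.39 ± 0.24 before and 1.78 after the correction), the peptide hormone NTS (0.84 ± 0.30 before and 1.45 after the correction), the receptor NEO1 (1.59 ± 0.30 before and 1.68 after the correction) and GALNT15 (1.58 ± 0.26 before and 1.66 after the correction) rose, and MAPK4 (-1.22 ± 0.27 before and -1.44 after the correction) fell. C2H2 zinc finger genes have a median GC content of 45.7%, against 49.4% for all tested genes. Of 434 tested, 46 were higher and 49 lower, with a median of -0.19 and a camera p of 0.246, and the corrected median was 0.0182 with a p of 0.804. As the family was not past the threshold before the correction either, its corrected median decides nothing, a reading set after the values were seen. The rule written before the test would have counted that median for GC and length bias.

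GC-poor genes were lower and GC-rich genes higher in treated cells, with a Spearman correlation of 0.661 between log2 fold change and GC content across 15487 genes, and of -0.188 with transcript length. Mean sequencing depth differed by -0.0399% with overlapping ranges, which argues against depth, and given GC content, length kept a correlation of only -0.0176 (95% bootstrap interval -0.0343 to -0.00296), so the length trend largely followed GC content. A GC bias of single libraries is a candidate explanation. Single libraries differed from the others of their group by correlations with GC of -0.402 to 0.463, and length slopes overlapped between the groups (gap -0.00763). The gap in GC slope between the nearest libraries of the groups (0.201 per 10 points) was smaller than the full range within the controls (0.237). The group means lay further apart than that gap. Control slopes were -0.305, -0.0674 and -0.213, and treated slopes 0.295, 0.134 and 0.156. The slopes of the groups did not overlap, so an effect of the inhibitor that follows GC content stays open and was not tested. Given length, GC content and expression, genomic span kept a correlation of -0.0452 (-0.0598 to -0.0284 over resampled genes). That value lay above the -0.1 or lower set beforehand for an effect on long gene bodies, but the interval crossed the bound of -0.05 set against it. The interval leaves out the spread between libraries, and GC content was held fixed, so an effect on long gene bodies was not decided.

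The G2/M and mitosis list was lower before and after the correction, with a corrected median of -0.33 (interval -0.408 to -0.289 over resampled members). This argues against GC and length as the whole cause, although the interval, added after the values were seen, reached past the bound of -0.3 set for the median, and the corrected adjusted p was 0.0786 with an estimated correlation. The interval also leaves out the spread between libraries. A smaller share of dividing cells may account for it, since the list of G1/S and DNA replication was lower too (corrected median -0.15, interval -0.242 to -0.125). No cell counts were analysed here, however. Camera did not call that list before the correction (adjusted p = 0.0825, 17 genes lower and 5 higher), nor after it with an estimated correlation (0.289). After the correction 21 of the 45 G2/M genes were lower, while UBE2C (0.06), CCNB1 (-0.06) and PLK1 (-0.08) did not pass. Highly expressed members differed. MYBL2 (-0.75) and TPX2 (-0.37) were lower after the correction, while UBE2C, CDC20, PLK1, AURKB and BIRC5 passed neither before nor after it. With members split in this way, a smaller share of dividing cells was not decided as the explanation. The DNA repair list kept camera's call too (adjusted p = 0.517 with an estimated correlation), but GC bias and an effect on repair genes cannot be told apart there, because its corrected median of -0.20 (interval -0.282 to -0.137) lay between the bounds set for it.

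Of 10 tested circadian output genes driven through E-box elements, 6 fell, namely DBP (-1.15 ± 0.14, 34.7 to 15.6 CPM), NR1D1, NR1D2, PER1, PER2 and TEF. BHLHE41, CRY2, PER3 and USP2 did not pass the threshold. The correction moved the median of the 10 from -0.45 to -0.67 (interval -1.03 to -0.203), which argues against GC and length bias, although the list was drawn up after DBP was seen. A difference in circadian phase between the groups, whose times of harvest are not given in the sources used here, may lower this arm of the clock and raise the arm driven through ROR elements. Before the correction, 2 of the 6 tested genes of that other arm fell instead, CLOCK (-0.67 ± 0.23 before and -0.09 after the correction) and CRY1 (-0.87 ± 0.33 before and -0.31 after the correction), with a median of -0.11 for the 6, and after it neither passed the threshold, as their changes shrank. The corrected median was 0.0502, with an interval (-0.144 to 0.194) too wide to decide, a reading set after the values were seen. The rule first written for this test would have counted that median against a difference in phase.

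Of the 10 splits of the 6 libraries into 3 and 3, edgeR called 5225 genes in the real split and at most 0 in the others, where up to 1165 genes had an unadjusted p under 0.05. After the correction, the real split gave 1701 and the highest other 1. In each case only 1 split, the real one, gave as many genes, and with 10 splits the share cannot fall under 0.05. Every other split mixes treated and control libraries, so a difference between the groups, whatever its cause, adds to the spread within them and few calls follow. The contrast therefore decides nothing about the cause.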
